A study of Drosophila melanogaster with 4 samples.

How the data were processed

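The series holds RNA-seq of total RNA from salivary glands of Drosophila melanogaster larvae in the third instar, raised in an incubator, with 2 wild-type libraries and 2 libraries from larvae of the JIL-1 null allele Z2. Per the labels' protocols, glands were dissected, RNA was isolated with a commercial kit and libraries followed the Illumina protocol. Reads were aligned with GSNAP, for which no version is given, and the genome builds named are BDGP5 and dm3, per the submitters' processing notes. The counter, the gene annotation, any use of strand, any filter on genes and the test behind the deposited p-values are not given in the sources used here.

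One deposited table was used. Its raw counts, whole numbers of reads per gene in each library, are as the authors deposited them, per the file headers. The pooled RPKM of each genotype, a fold or ratio of mutant over wild type, a p-value and a false discovery rate per gene are the authors' deposited values, per the file headers, and were used only to describe the authors' own comparison. The table lists 9931 genes, all with a name, the lowest total of a gene is 3 counts, and each gene has counts in at least 2 libraries. All 4 count columns were matched to samples by name. The available reference annotation was of another build (BDGP6.54, Ensembl release 115), so no coordinates are printed. It was used to match older and newer symbols by gene identifier, which succeeded for 9523 identifiers and not for 408, and to look up chromosome arms.

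Library totals ran from 6222322 to 11369094 counts. Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) with TMM factors. The factors were 1.028, 0.931, 1.003 and 1.042 for wild type libraries 1 and 2 and JIL-1 null libraries 1 and 2. The filterByExpr function kept genes with enough counts, with a count minimum of 10 in 2 libraries and a total minimum of 15, which left 7958 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, and calls were made at 0.05. The biological coefficient of variation was 14.9%, with 2 residual and 4.08 prior degrees of freedom. Fitted log2 fold changes use a prior count of 0.125. Standard errors of log2 fold changes were derived from the F statistic of the edgeR test. CPM are counts scaled to library size with TMM factors. A level of 3 counts corresponds to between 0.264 and 0.482 CPM of the deposited totals, and was taken per library as the limit of detection. Genes with 0 counts in a genotype have a fold only as a bound against that limit. Genes with 1 to 3 counts have a ratio with an exact 95% interval, and such intervals cover counting error only.

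The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took JIL-1, then the 10 higher and 10 lower genes with the largest fold change among called genes with a mean of at least 5 CPM, no overlap between genotypes and a symbol other than a number. It added 2 higher and 2 lower genes known only by a number. It also added up to 2 higher and 2 lower called members of each list by smallest adjusted p, or the 2 most abundant members where none was called. More members were allowed, by the same order, for the glue, ecdysone early and dosage compensation lists. Some genes that this rule selects are not reported here. Other genes named in the text were chosen after their values were seen, to complete counts of 5 or fewer or as well-known members of a list. The 29 lists cover glue genes, gland identity, ecdysone early and late genes, dosage compensation, heterochromatin, interband proteins, Polycomb and Trithorax, homeotic genes, heat shock, the secretory pathway, replication, cell death and immune genes. They also cover ribosomal proteins, the proteasome, tRNA synthetases, cytochrome P450, glutathione S-transferases, oxidative phosphorylation, markers of fat body, haemocytes, muscle, midgut, neurons, cuticle, testis and ovary, and Y-linked genes. The 27 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01 and adjusted over lists. The homeotic list had 2 tested members and the Y-linked list had 0 genes in the table. Camera called 3 lists higher and 4 lower. With an estimated correlation it called 0, as did fry (rotation test of limma 3.58.1), while fry's mixed test, which asks whether members change in either direction, called 25. Scr stands in 2 of the lists, as do Cyp18a1, piwi and Su(var)3-3. The share of higher genes was compared between 4 equal bins of mean log2 CPM by Fisher's exact test.

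The procedure was tested on simulated data, with counts for the 7958 genes drawn from the means of the real libraries, 200 genes changed singly and a further list of 30 genes shifted 2-fold together, of which 24 were called. In that simulated comparison 79% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, with 0 called in the wrong direction. Of 227 calls 24 were unchanged genes, or 10.6%, above the nominal rate. Camera called the shifted list and 0 of 26 unchanged lists. The simulated genes varied independently, so this does not test camera where members of a list vary together. In the real libraries the estimated correlation was 0.534 for the late ecdysone list and 0.743 for the midgut list, but -0.00941 for the early ecdysone list. That last value lies below the preset of 0.01, yet the unadjusted camera p of the early list went from 9.33e-07 to 0.0319. With an estimated correlation camera uses only the 2 residual degrees of freedom, so it could hardly pass any of the 27 lists. Its adjusted p of 0.798 for a list therefore decides little. Far fewer genes were changed in the simulation than the 30.7% called in the real comparison.

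The alternatives were RLE and upper quartile scaling, TMM without 13 genes, no filter and a mean of at least 5 CPM. The 13 genes were all listed glue genes, whatever their level, and any other gene above 2% of a library. Further alternatives were DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, and a threshold of 0.01. The lists were also run with an estimated correlation and with fry. The planned test of chromosome arms needed positions of the authors' build, so arms were instead looked up by gene identifier in the other build, a choice made after the data were seen. Of the tested genes 7611 had an arm and 347 did not. With 2 libraries per genotype, no test of an outlying library within a genotype and no count over other splits of the samples applied. Paralogs with near-identical sequence (the Hsp70, Lsp1, Lys and RpS14 genes, U3 small nucleolar RNA) and overlapping or antisense genes have uncertain counts, since the treatment of shared reads and of strand is not given in the sources used here.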

Results

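RNA-seq was carried out on salivary glands of Drosophila melanogaster larvae in the third instar. The glands came from wild-type larvae and from larvae without functional JIL-1, a chromosomal kinase that phosphorylates histone H3 and is found in the open interband regions of polytene chromosomes. Each genotype had 2 libraries. The deposited counts summed to 6222322 and 8496047 in wild type libraries 1 and 2, and to 8071769 and 11369094 in JIL-1 null libraries 1 and 2. The table listed 9931 genes, of which 8983 had a count in all 4 libraries. Glue genes, which encode the secretion that fixes the pupa to its substrate, took 35.6% and 37.96% of the counts in wild type and 38.2% and 37.1% in JIL-1 null. Sgs3, Sgs5, Sgs7, Eig71Ee and Sgs4 together held between 31.5% and 34.9% of each library. Counts of the libraries of one genotype differed by more than sampling noise, with a chi-square per degree of freedom of 23.4 in wild type and 9.17 in JIL-1 null, so each was kept as a sample of its own. Between genotypes the same quantity lay between 80.3 and 113. The labels do not say that the libraries of a genotype came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

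JIL-1 itself (FBgn0020412) was measured first, as a check of the labels. Its level fell from 85.2 ± 11.7 CPM in wild type to 55.6 ± 0.182 CPM in JIL-1 null (SD, n = 2 each; CPM are counts scaled to library size with TMM factors). The log2 fold change was -0.61 ± 0.12 (adjusted p = 0.0147 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Here and below, log2 fold changes are JIL-1 null over wild type and their errors are standard errors. The JIL-1 counts were 597 and 608 in wild type and 449 and 660 in JIL-1 null. Counts per gene do not say which part of the gene the remaining reads came from, so this level is only a limited check of the mutant label. With JIL-1 null library 1 left out the log2 fold change was -0.60 (adjusted p = 0.108), and with library 2 left out it was -0.64 (adjusted p = 0.121), by the same edgeR test. Over all alternatives the adjusted p ran from 0.00316 to 0.121.

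The comparison of JIL-1 null with wild type asked which transcripts differ between glands of the 2 genotypes. Strain and genotype are the same split in this design, and stage or carried-over tissue may differ with them. The changes below can therefore not be assigned to loss of JIL-1 alone. The larval storage protein gene Lsp1gamma, the stress-induced humoral factor gene TotA, the cell adhesion gene Dscam4 and several late ecdysone-induced genes of the 71E puff were far higher in JIL-1 null. The peptide transporter gene yin, the immune gene AttD, the cytochrome P450 gene Cyp6d5 and the uncharacterised gene CG3397 were far lower. Of 7958 genes tested, 1077 rose and 1369 fell in JIL-1 null (adjusted p under 0.05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), so that 44.0% of the called genes were higher. The called genes made up 30.7% of those tested, the share beside which the counts of called list members below stand. By at least 2-fold, 429 genes rose and 714 fell. With upper quartile scaling, which moved the median log2 fold change of all genes from 0.03 to 0.17, 1690 genes rose and 1154 fell, and 59.4% of the called genes were higher. The groups did not overlap for 5593 genes (70.3% of those tested), where chance alone gives 33.3% with 2 libraries against 2. Without JIL-1 null library 1 the counts were 282 higher and 629 lower, and without JIL-1 null library 2 they were 195 higher and 524 lower.

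Among the 10 named genes with the largest increase, mthl8, a methuselah-like receptor gene, had no counts in wild type and 232 in JIL-1 null, at least 27.7-fold higher. Eig71Ei of the 71E puff had no wild-type counts and 203 in JIL-1 null, at least 24.3-fold higher. Both bounds set the wild-type level at 3 counts in each library. Lsp1gamma rose from 7.48 ± 0.168 to 4335 ± 622 CPM (SD, n = 2), a log2 fold change of 9.18 ± 0.21 with adjusted p = 6.17e-05 by edgeR's quasi-likelihood test. It has the paralogs Lsp1alpha and Lsp1beta, with which reads can be shared. Elo68alpha, a fatty acid elongase gene, had 1 count in wild type and 259 in JIL-1 null, a ratio of 186 with a 95% counting interval from 33.0 to 7364. TotA rose 119-fold, from 5.30 ± 0.196 to 636 ± 139 CPM (log2 fold change 6.90 ± 0.23). Dscam4 rose from 1.07 ± 0.631 to 98.9 ± 10.3 CPM, and Eig71Ef from 5.37 ± 5.83 to 214 ± 73.0 CPM. The neuronal cell surface genes dpr and CadN reached 46.1 ± 4.56 and 13.1 ± 0.419 CPM in JIL-1 null, with log2 fold changes of 4.82 ± 0.26 and 4.33 ± 0.33. The U3 small nucleolar RNA gene snoRNA:U3:54Ab, a member of a family of near-identical copies, had a log2 fold change of 4.21 ± 0.30. Of the genes known only by a number, CG13560 rose from 20.8 ± 5.38 to 2007 ± 244 CPM (log2 fold change 6.60 ± 0.24). CG6761 had a log2 fold change of 6.51 ± 1.26, with 33.4 ± 32.9 CPM in JIL-1 null.

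Among the genes that fell, CG3397 dropped from 1519 counts in wild type to 1 in JIL-1 null, a ratio of 2118 with a 95% counting interval from 380 to 83719. The peptide transporter gene yin fell from 19.8 ± 0.506 to 0.289 ± 0.290 CPM (SD, n = 2; log2 fold change -6.20 ± 0.41, adjusted p = 0.000450 by edgeR's quasi-likelihood test). The noncoding RNA gene pncr009:3L had a log2 fold change of -5.64 ± 0.22, and Map205, which encodes a microtubule-associated protein, one of -4.89 ± 0.23. Cyp6d5 fell from 75.5 ± 9.88 to 2.84 ± 0.186 CPM. AttD, of the attacin family of antibacterial peptides, had a log2 fold change of -5.55 ± 0.69. Hsp70Ba, at -4.51 ± 0.71, belongs to a family of near-identical heat shock genes between which reads can be split. For nol, 534 counts in wild type stood against 2 in JIL-1 null (ratio 372, 95% counting interval from 103 to 3082), and 489 of the 534 came from wild type library 2. CG14850 had 216 and 14 counts in the wild-type libraries and 0 in JIL-1 null. It was at least 53.5-fold lower for the pooled wild-type counts, a bound that rests on library 1, since library 2 stood at 1.77 CPM. With limma-voom nol, CG14850 and the raised gene CG6761 kept their direction but did not pass the threshold, with adjusted p = 0.245, 0.212 and 0.245, and AttD had adjusted p = 0.0517. These were the highest of all alternatives, and the lowest were 1.85e-10 for nol, 0.000194 for CG14850, 0.00136 for CG6761 and 3.2e-15 for AttD. The digestive enzyme genes LysD (12 and 603 counts in wild type libraries 1 and 2), Jon25Bii (8 and 455) and epsilonTry (12 and 146) also passed the test. Without wild type library 2 their log2 fold changes were -1.73, -1.06 and -1.79, with adjusted p = 0.179, 0.446 and 0.212 by the edgeR test, and over all alternatives their highest adjusted p were 0.434, 0.446 and 0.218.

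**Figure D1:**
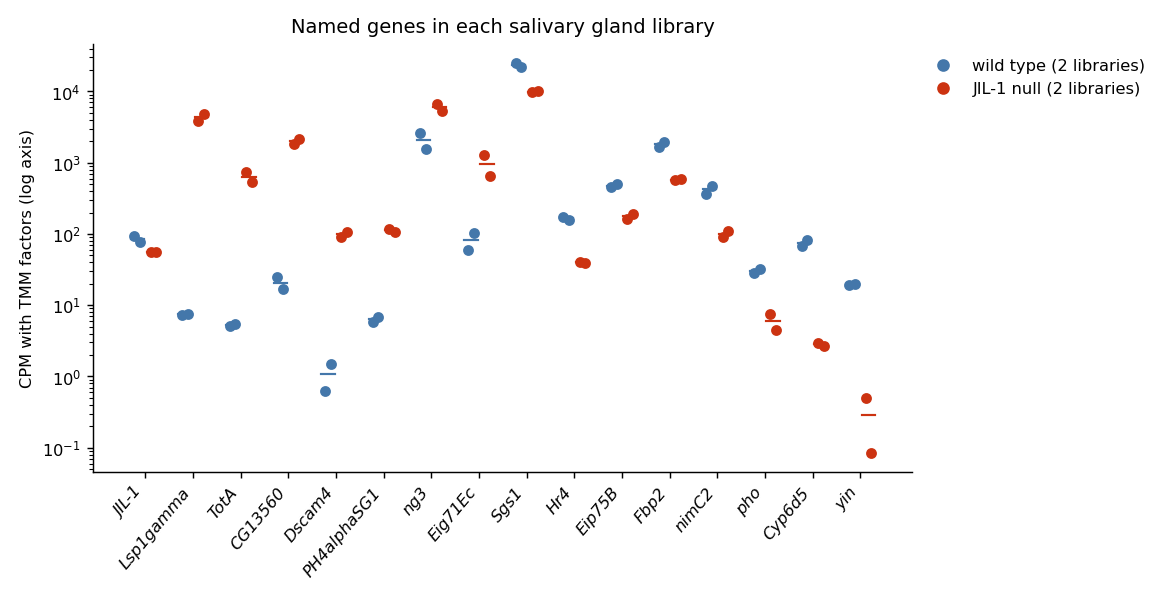
CPM with TMM factors (log axis) of 16 named genes, with a point for each of the 2 wild-type and 2 JIL-1 null libraries and a bar at the mean of each genotype. Lsp1gamma has a mean of 7.48 CPM in wild type and 4335 CPM in JIL-1 null, and yin 19.8 and 0.289 CPM.

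The late genes of the 71E puff, which ecdysone induces in the gland after the glue genes, had the highest median fold change of the lists tested. All 10 listed members were tested, and 9 rose and 1 fell, with the same numbers adjusted over the list alone. Eig71Ec rose from 81.0 ± 31.5 to 973 ± 454 CPM (SD, n = 2), a log2 fold change of 3.58 ± 0.42. The exception was Eig71Eg, which fell from 61.1 ± 30.4 to 20.6 ± 0.568 CPM. The median log2 fold change of the list was 4.20, or 4.10 with Eig71Ei set at its bound. Camera with its preset correlation called the list higher than other genes (adjusted p = 7.50e-07), and adjusted p = 0.798 with an estimated correlation.

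Ecdysone receptor and early response genes moved the other way. Of 25 tested, 14 fell and 2 rose over all genes, and 16 fell and 2 rose adjusted over the list alone. Not all of the 14 are receptor or early puff genes. They include shd and Cyp18a1, of hormone synthesis and breakdown, at -0.99 ± 0.21 and -3.41 ± 0.74 on the log2 scale, and ImpL2 and ImpL3. The nuclear receptor genes Hr4 and Eip78C fell by 2.05 and 1.65 on the log2 scale, from 165 ± 9.98 to 40.0 ± 0.772 CPM and from 288 ± 12.3 to 91.9 ± 6.42 CPM (SD, n = 2). ImpL3, which encodes lactate dehydrogenase, had a log2 fold change of -1.71 ± 0.12. Members chosen after their values were seen, because they are standard early genes, gave log2 fold changes of -1.42 ± 0.13 for Eip75B, -0.98 ± 0.11 for Eip74EF, -0.82 ± 0.11 for br and -0.47 ± 0.10 for the receptor gene EcR. All 4 of these passed the test. The genes that rose were Hr46, at 0.81 ± 0.18, and Eip63E, at 0.87 ± 0.22. The median was -0.82 (camera adjusted p = 1.26e-05, and adjusted p = 0.798 with an estimated correlation).

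Of the 12 glue and intermoult secretion genes, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone. The 4 were the ng genes, which are expressed before the main glue genes. Of these, ng3 rose from 2071 ± 756 to 6053 ± 943 CPM (SD, n = 2), and ng1 and ng2 had log2 fold changes of 1.92 ± 0.40 and 1.76 ± 0.45. The fourth, ng4, had 2 counts in wild type and 34 in JIL-1 null, a ratio of 12.2 with a 95% counting interval from 3.13 to 105, and was not called by DESeq2 (adjusted p = 0.0545; range over all alternatives 0.0132 to 0.121). Sgs1 fell from 23455 ± 1785 to 9880 ± 175 CPM. The most abundant glue genes did not pass the test, with log2 fold changes of 0.44 ± 0.15 for Sgs3, -0.10 ± 0.20 for Sgs5, -0.13 ± 0.22 for Sgs7 and -0.07 ± 0.15 for Sgs4. The list was not called by camera (adjusted p = 0.373); its median was -0.07, its mean 0.59 and the direction of the test upward, and with upper quartile scaling the median was 0.07. Without wild type library 2 the median was 0.33 and camera called the list higher (adjusted p = 0.0308).

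Among 11 genes of gland identity, 2 rose and 2 fell, over all genes and adjusted over the list alone. The prolyl hydroxylase genes PH4alphaSG1 and PH4alphaSG2, expressed in salivary glands, rose from 6.31 ± 0.738 to 112 ± 6.73 CPM and from 126 ± 13.1 to 364 ± 13.1 CPM (SD, n = 2). The gland transcription factor gene sage had a log2 fold change of -0.54 ± 0.14, and mav, which encodes a ligand of the TGF-beta family and may not be a gene of gland identity, one of -1.32 ± 0.28. Camera did not call this list (adjusted p = 0.0658), but did without wild type library 1 (adjusted p = 0.0327) and without JIL-1 null library 2 (adjusted p = 0.04897), and with all 4 libraries without a filter (adjusted p = 0.0323) and at a mean of at least 5 CPM (adjusted p = 0.0210). Its median was -0.05, or 0.08 with upper quartile scaling, its mean was 0.31 and the direction of the test was upward.

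**Figure D2:**
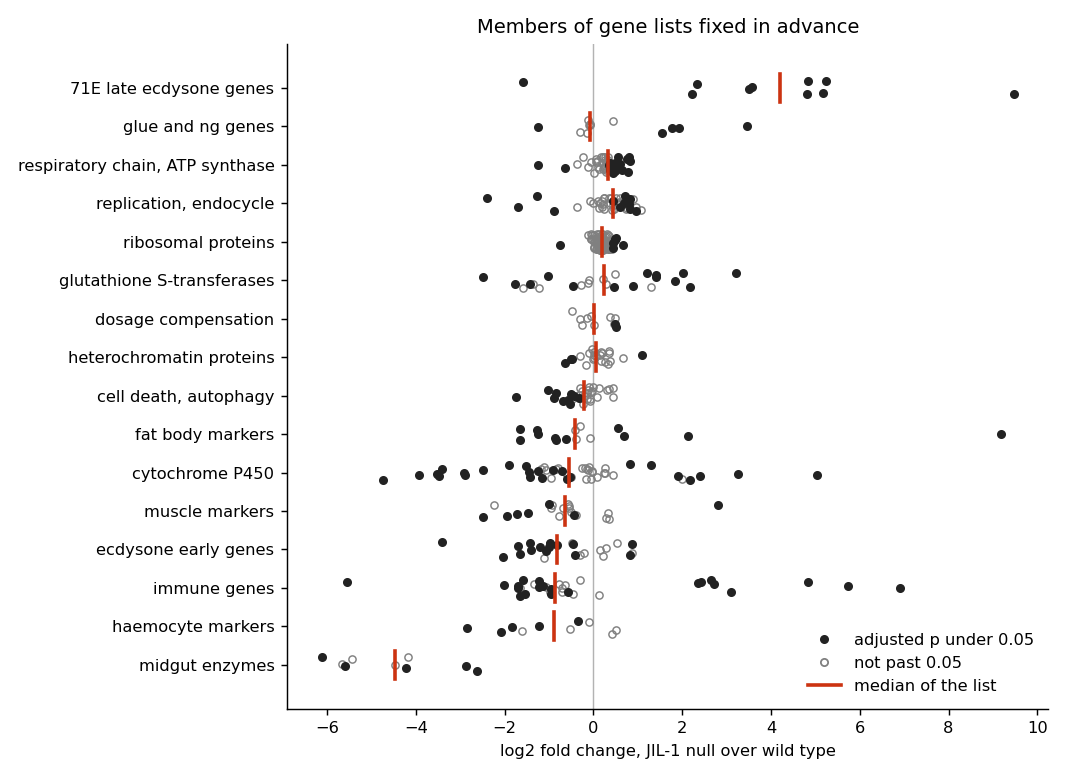
Log2 fold change (JIL-1 null over wild type, x axis) of the tested members of 16 gene lists, 1 row per list, with filled points for genes with adjusted p under 0.05, open points for the others and a bar at the median of each list. The 71E late genes have a median of 4.20 and the midgut enzymes one of -4.46, while the other medians lie between -0.88 and 0.44.

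Of 60 tested subunits of the respiratory chain and ATP synthase, 26 rose and 2 fell, or 32 and 2 adjusted over the list alone. ATPsyn-d rose from 64.8 ± 1.49 to 113 ± 8.39 CPM and RFeSP from 61.6 ± 1.38 to 105 ± 7.16 CPM (SD, n = 2). The 2 that fell were CG40002 and CG32230, at -1.24 ± 0.20 and -0.64 ± 0.15 on the log2 scale. The median log2 fold change of the list was 0.34, and camera called it higher (adjusted p = 0.000368, and adjusted p = 0.798 with an estimated correlation). Of 80 cytosolic ribosomal protein genes, 6 rose and 1 fell, and 0 of either passed in edgeR adjusted over the list alone, against 19 higher and 1 lower at an unadjusted p under 0.05. DESeq2 called 9 of these higher and 1 lower, and limma-voom 8 and 1. By edgeR over all genes the share called was 8.75%, against 46.7% of the respiratory chain and ATP synthase list and 30.7% of all tested genes. The gene that fell was RpS14b, which has a near-identical copy in RpS14a, at -0.76 ± 0.17. The median of these genes was 0.20, and 74 of 80 were above 0 (camera adjusted p = 0.00796, and adjusted p = 0.798 with an estimated correlation). Without wild type libraries 1 and 2 in turn the median was 0.09 and 0.31. The camera adjusted p for ribosomal proteins was 0.132 without wild type library 1, and its lowest value over the alternatives was 2.11e-06.

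Cytochrome P450 genes, which encode oxidases of hormones and foreign compounds, fell more often than they rose. Of 48 tested, 18 fell and 7 rose, or 22 and 8 adjusted over the list alone. Cyp6d5 and Cyp309a1 fell by 4.74 and 3.52 on the log2 scale, the latter from 55.3 ± 0.0420 to 4.87 ± 0.799 CPM (SD, n = 2). Cyp6g1 rose from 5.16 ± 0.217 to 23.2 ± 0.851 CPM, and Cyp9c1 had a log2 fold change of 0.82 ± 0.12. The median was -0.56 (camera adjusted p = 0.00117, and adjusted p = 0.798 with an estimated correlation). Of 24 glutathione S-transferase genes, 9 rose and 5 fell, or 11 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.153) except at a mean of at least 5 CPM (adjusted p = 0.0491). GstE1 rose from 5.12 ± 2.60 to 48.7 ± 2.74 CPM and GstD9 from 5.02 ± 0.238 to 22.8 ± 2.67 CPM. CG6776 and GstE9 fell, at -2.50 ± 0.17 and -1.77 ± 0.31, as did GstE7, GstE3 and GstS1.

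Markers of other larval tissues were measured beside those of the gland. Of 15 fat body genes, 4 rose and 7 fell, or 4 and 9 adjusted over the list alone. Fbp2 fell from 1822 ± 222 to 579 ± 19.1 CPM (SD, n = 2), and Lsd-1, a lipid droplet gene, from 345 ± 78.0 to 110 ± 5.11 CPM. Besides Lsp1gamma, the genes that rose were CG15828 (log2 fold change 0.69 ± 0.10), CG6188 (0.55 ± 0.11) and tobi (2.12 ± 0.64). Abundant members chosen after their values were seen had log2 fold changes of -1.25 ± 0.16 for Fbp1 and -0.84 ± 0.14 for Lsp2, which passed the test, and of -0.41 ± 0.13 for Lsp1beta and -0.09 ± 0.13 for Lsp1alpha, which did not. The list was not called by camera (adjusted p = 0.732); its median was -0.41, its mean 0.21 and the direction of the test downward.

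Of 10 haemocyte markers, 5 fell, or 5 down and 1 up adjusted over the list alone. BM-40-SPARC, a basement membrane gene, fell from 124 ± 8.202 to 34.6 ± 1.58 CPM (SD, n = 2) and nimC2, a gene of the Nimrod receptor family, from 422 ± 78.7 to 99.9 ± 13.1 CPM. The others were srp (-1.22 ± 0.13), Hml (-2.84 ± 0.59) and crq (-0.35 ± 0.09). Hml stood at only 2.94 CPM in wild type, and the listed markers He, eater, nimC1 and Sr-CI had too few counts to be tested. The tissue behind the more abundant members was not measured, so these falls need not be a loss of haemocyte transcripts. The collagen genes Cg25C and vkg, at 0.41 ± 0.16 and 0.51 ± 0.17, did not pass the test over all genes. The list median was -0.88, or -0.50 without wild type library 1 and -1.52 without JIL-1 null library 2 (camera with all libraries adjusted p = 0.01001, and adjusted p = 0.798 with an estimated correlation). With limma-voom the adjusted p was 0.0517, and the lowest over the alternatives was 0.00201.

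Of 9 midgut digestive enzyme genes tested, 5 fell, or 9 adjusted over the list alone, and without wild type library 2 only Mal-A6 and LysP fell in the edgeR test, over all genes and adjusted over the list alone. Mal-A6, a maltase gene, fell from 62.9 ± 4.44 to 8.59 ± 0.439 CPM (SD, n = 2), and the lysozyme gene LysP from 34.2 ± 0.163 to 5.62 ± 1.85 CPM. In wild type libraries 1 and 2 Mal-A6 stood at 59.8 and 66.1 CPM and LysP at 34.3 and 34.0 CPM. These 2 genes did not share the excess of the other listed genes in library 2, so their falls need not come from midgut. The falls of the other 7 rest on wild type library 2. Without it alphaTry and betaTry had log2 fold changes of 3.00 and 1.35, against -4.46 and -4.17 with all libraries, and Jon65Aiii and Jon65Aiv were at -0.70 and -0.31, against -5.44 and -5.67. The 25 listed genes in the table summed to 116 CPM in wild type library 1, 974 CPM in wild type library 2, and 30.5 and 28.8 CPM in JIL-1 null libraries 1 and 2. The list median was -4.46, or -1.06 without wild type library 2 (camera with all libraries adjusted p = 0.000926, and adjusted p = 0.798 with an estimated correlation). The camera adjusted p was 0.0517 with limma-voom and 0.0565 without wild type library 2, and the lowest over the alternatives was 1.28e-46, without wild type library 1. Without wild type library 2 the counts over all genes were 861 higher and 1162 lower.

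Of 20 muscle genes, 1 rose and 6 fell, or 2 and 6 adjusted over the list alone. TpnC73F and Strn-Mlck fell by 2.495 and 1.472 on the log2 scale, and Mlc1, a myosin light chain gene, rose from 5.03 ± 0.852 to 35.1 ± 2.30 CPM (SD, n = 2). Strn-Mlck stood at 571 CPM in wild type, against 13.1 CPM of Mhc and 5.73 CPM of Mf, which did not pass the test. Its fall need therefore not come from muscle. The neuronal genes Syt1, Sh and Syx1A fell among 6 tested, with log2 fold changes of -1.27 ± 0.18, -1.62 ± 0.25 and -0.74 ± 0.21, and the same 3 passed adjusted over the list alone. Of 12 cuticle and tracheal genes, Cpr49Ac (-1.41 ± 0.13) and serp (-0.93 ± 0.23) fell, and 2 fell adjusted over the list alone. Camera called none of these 3 lists, with adjusted p = 0.209, 0.304 and 0.266, but it called the muscle list without wild type library 2 (adjusted p = 0.0274) and the cuticle list without JIL-1 null library 1 (adjusted p = 0.00870). The cuticle median was -0.45, or -1.54 and -0.08 without JIL-1 null libraries 1 and 2 in turn. The cuticle protein gene Lcp1 had 84 and 83 counts in the first library of wild type and JIL-1 null, and 2 and 4 in the second, and Lcp2 and Lcp4 were also higher in the first library of each genotype.

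Immune genes changed in both directions. Of 32 tested, 8 rose and 13 fell, or 8 and 16 adjusted over the list alone. CecC, an antibacterial cecropin gene, rose from 13.7 ± 1.62 to 90.1 ± 8.27 CPM (SD, n = 2), beside TotA. The recognition gene PGRP-SA and pirk, a negative regulator of the Imd pathway, fell by 1.54 and 1.22 on the log2 scale. The list was not called (camera adjusted p = 0.732); its median was -0.86, its mean 0.01 and the direction of the test downward. Of 18 heat shock and chaperone genes, 2 rose and 3 fell, with the same numbers adjusted over the list alone. Hsp70Bc (3.74 ± 0.81) and Hsp60 (0.70 ± 0.17) rose, and Hsp70Ba, Hsp23 (-0.69 ± 0.13) and Hsp27 (-0.67 ± 0.15) fell, with the Hsp70 copies uncertain because of shared reads. JIL-1 null library 1 stood apart for inducible genes, with 83.6 CPM of Hsp70Bc against 19.5 in JIL-1 null library 2, and 183 against 20.5 CPM of Hsp68, which did not pass the test. With limma-voom Hsp70Bc did not pass either (adjusted p = 0.107), and its lowest over the alternatives was 0.00422. Camera gave adjusted p = 0.880 for this list, and adjusted p = 0.0204 without JIL-1 null library 2.

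Of 31 genes of the endoplasmic reticulum and secretory pathway, 6 rose and 1 fell, with the same numbers adjusted over the list alone. The protein disulfide isomerase gene ERp60 rose from 1149 ± 155 to 2188 ± 2.00 CPM (SD, n = 2), and CaBP1 had a log2 fold change of 0.65 ± 0.13. Herp was at -0.45 ± 0.11. Of 42 replication and endocycle genes, 8 rose and 4 fell, again the same adjusted over the list alone. The PCNA gene mus209 and the ribonucleotide reductase gene RnrL rose by log2 fold changes of 0.82 ± 0.17 and 0.83 ± 0.18. The mitotic genes polo (-2.39 ± 0.47) and stg (-1.70 ± 0.37) fell, as did Psf1 (-1.28 ± 0.20) and the Cdc7 kinase gene l(1)G0148 (-0.89 ± 0.23). Of 32 cell death and autophagy genes, 10 fell and 0 rose in edgeR, the same adjusted over the list alone, and 13 were lower and 0 higher at an unadjusted p under 0.05. DESeq2 called 8 lower and limma-voom 10. They included the initiator caspase gene Nc (-1.75 ± 0.17) and Atg7 (-0.90 ± 0.11). Of the secretory, replication and cell death lists 22.6%, 28.6% and 31.25% were called by edgeR, against 30.7% of all tested genes. Camera called none of the secretory, replication and cell death lists, with adjusted p = 0.144, 0.0658 and 0.104. Without wild type library 1 it called the secretory list (adjusted p = 0.0188) and the replication list (adjusted p = 0.00537), and the latter also without JIL-1 null library 1 (adjusted p = 0.0277). With all 4 libraries it called the replication list without a filter (adjusted p = 0.0461), at a mean of at least 5 CPM (adjusted p = 0.0495) and with limma-voom (adjusted p = 0.00509), and the cell death list with limma-voom (adjusted p = 0.0134).

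Among 22 aminoacyl tRNA synthetase genes, CG15100, Aats-ala, Aats-leu, Aats-thr and Aats-lys rose and Aats-trp fell, or 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.266). Of 31 proteasome genes, Pros25 rose from 59.2 ± 1.13 to 113 ± 5.23 CPM (SD, n = 2) and Prosbeta2 fell by 0.42 on the log2 scale, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.886). Of the tRNA synthetase and proteasome genes 27.3% and 6.45% were called by edgeR, against 30.7% of all tested genes. The proteasome median was -0.04 and its mean -0.02, with the test upward, and the median was 0.10 with upper quartile scaling. By edgeR, 0 of 6 testis genes passed the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.358), against 1, Mst36Fa, at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, although Mst36Fa passed with upper quartile scaling (adjusted p = 0.0420). Of 8 germline genes, cuff (1.04 ± 0.26) and armi (1.00 ± 0.27), both of the piRNA pathway, rose, and 2 rose adjusted over the list alone (camera adjusted p = 0.274). DESeq2 did not call armi (adjusted p = 0.159), whose adjusted p over all alternatives ran from 0.0206 to 0.199. The homeotic genes Scr and Antp, the only ones tested, were at -0.17 ± 0.31 and -0.85 ± 0.32 and did not pass over all genes or adjusted over the list alone, by edgeR, DESeq2 or limma-voom, although Antp was under 0.05 unadjusted.

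Of 11 dosage compensation genes, Top2 (0.52 ± 0.11) and msl-2 (0.49 ± 0.14) rose, and 1 rose adjusted over the list alone. DESeq2 called 0 of this list, with adjusted p = 0.0535 for Top2 and 0.215 for msl-2, and limma-voom called these 2. Over all alternatives the adjusted p ran from 0.00843 to 0.194 for Top2 and from 0.0198 to 0.232 for msl-2. The noncoding RNA genes roX1 and roX2, at -0.49 ± 0.23 and 0.47 ± 0.29, did not pass the test. Of 23 heterochromatin genes, HP4 rose from 3.74 ± 0.461 to 7.98 ± 0.774 CPM (SD, n = 2), and Su(var)3-7 (-0.49 ± 0.11), wde (-0.51 ± 0.14) and SuUR (-0.65 ± 0.19) fell. In edgeR, 0 rose and 0 fell adjusted over the list alone, against 1 and 3 at an unadjusted p under 0.05, 1 and 3 called by limma-voom and 0 by DESeq2. Of 17 interband and chromosome architecture genes, the remodeller gene Iswi rose (0.75 ± 0.20), and BEAF-32 (-0.64 ± 0.09) and Acf1 (-0.46 ± 0.13) fell, or 0 up and 1 down adjusted over the list alone. Of 29 Polycomb and Trithorax genes, trx rose (0.48 ± 0.11), and pho, which encodes a DNA-binding Polycomb protein, fell from 30.3 ± 2.39 to 5.99 ± 2.02 CPM. Set1, a histone H3 methyltransferase gene, also fell, at -0.89 ± 0.11, so that 3 of the 29 were called. Adjusted over the list alone 0 rose and 2 fell. Called were 18.2% of the dosage compensation, 17.4% of the heterochromatin, 17.65% of the interband and 10.3% of the Polycomb and Trithorax genes. The share over all tested genes was 30.7%. DESeq2 did not call Iswi, Acf1 or trx. Camera called none of these 4 lists, with adjusted p = 0.702 for the first 3 and 0.886 for the Polycomb and Trithorax list, whose median was 0.03 and mean -0.03. With upper quartile scaling the falls of wde, Acf1, sage, Herp and Prosbeta2 kept their direction but were no longer past the threshold, with edgeR adjusted p from 0.0589 for sage to 0.0981 for Acf1. Over all alternatives the adjusted p of sage ran from 0.00101 to 0.260 and that of Acf1 from 0.0334 to 0.260.

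The direction of change varied with expression level. Among the called genes of the top of 4 equal bins by mean log2 CPM, which holds the abundant glue genes, 241 rose and 504 fell, so that 32.35% were higher. In the bottom bin 249 rose and 216 fell, or 53.55% higher, and the bins between gave 41.5% and 54.2%, the latter nearer the bottom. The odds ratio of being higher in the top against the bottom bin was 0.415 (95% interval 0.325 to 0.530, p = 3.93e-13, Fisher's exact test, two-sided, across genes, which are not independent replicates). With upper quartile scaling the shares were 50.5% in the top and 62.3% in the bottom bin, and with DESeq2 27.3% and 43.05%. Without JIL-1 null libraries 1 and 2 in turn the top bin gave 18.0% and 16.4%, and the odds ratio was 0.179 and 0.115. Without wild type libraries 1 and 2 in turn the bottom bin gave 43.55% and 46.4% and the top bin 34.6% and 37.7%, and the odds ratio was 0.686 and 0.701.

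**Figure D3:**
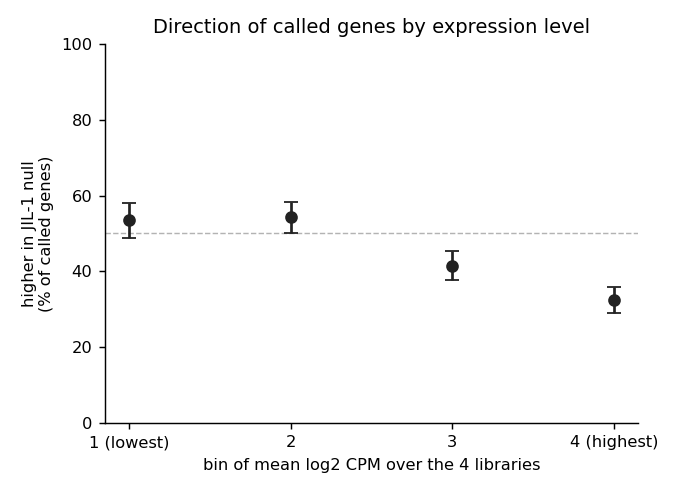
Share of genes higher in JIL-1 null among called genes (%, y axis) in 4 equal bins of mean log2 CPM over the 4 libraries (x axis), with exact 95% binomial intervals as bars and a dashed line at equal shares. The share is 53.55% in the lowest and 32.35% in the highest bin.

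The authors' deposited table gave 3742 genes at a false discovery rate under 0.05, of which 2241 were higher and 1501 lower in the mutant, or 59.9% higher. By at least 2-fold, the authors' deposited table held 761 higher and 778 lower genes. Of the genes called here, 2392 were called in the same direction in the authors' deposited table, 54 were not called there and 0 were called in the opposite direction. A further 1083 genes tested here were called in the authors' deposited table alone. For JIL-1 the authors' deposited table gave a fold of 0.706 at a false discovery rate of 0.0196, and for Lsp1gamma a fold of 628. Over 1709 well-counted genes, folds in the authors' deposited table were a median of 1.002 times the ratio of pooled counts scaled by the upper quartile, and 1.082 times that scaled by TMM.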

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

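No call of the edgeR test over all genes changed direction in any alternative, and of the 100 named genes past the threshold (JIL-1 aside) 46 stayed past it in every alternative and 78 in every one that kept all 4 libraries. Leaving out a library leaves 1 sample in a genotype, which is then assumed to vary like the other genotype. Without each library in turn, the log2 fold change of JIL-1 ran from -0.75 to -0.47, the genes higher from 195 to 1186, the genes lower from 524 to 1612, and the genes changed by at least 2-fold from 176 to 507 higher and from 474 to 835 lower. The share of called genes that were higher ran from 43.55% to 63.2% in the lowest of 4 expression bins and from 16.4% to 37.7% in the highest. The lists called higher ran from 4 to 5. JIL-1 was not past the threshold without JIL-1 null library 1 or 2. Upper quartile scaling gave 1690 higher genes and shares of 62.3% and 50.5% in the lowest and highest bins, since it shifts the median log2 fold change of all genes by 0.13. DESeq2 gave 587 higher genes and shares of 43.05% and 27.3%, and the highest bin held 28.4% with RLE scaling and 37.2% without a filter; the cause was not tested. A threshold of 0.01 left 321 higher and 756 lower genes. A mean of at least 5 CPM left 253 genes higher by at least 2-fold, because fewer low genes were tested, and 6 lists higher, against 5 without a filter. With an estimated correlation 0 lists were called higher and 0 lower, and fry called 0 higher and 0 lower. The list tests were not run with DESeq2. Uncalled results also turned. The proteasome list had adjusted p = 0.726 with limma-voom and 0.819 with fry, the heat shock list 0.974 and the Polycomb and Trithorax list 0.584 with fry, and arm 2R 0.976 without a filter and 0.988 with limma-voom, each in the other direction; the cause was not tested. With libraries left out, adjusted p ran from 0.0204 to 0.754 for heat shock, from 0.1403 to 0.928 for immune genes, from 0.00870 to 0.787 for cuticle genes, from 0.675 to 0.979 for Polycomb and Trithorax, and from 0.491 to 0.917 for the proteasome, and from 0.912 to 0.993 for arms 2R and 3L alike, and the log2 fold change of Scr from -0.66 to 0.21. The replicate numbers are shared between genotypes but the labels name no shared day or litter, and deviations of same-numbered libraries had a correlation of -0.0543 across 7958 genes. A value over all genes cannot show an effect confined to a few. ImpE2 of the ecdysone early list had 118 and 12 counts in wild type libraries 1 and 2, and 265 and 40 in JIL-1 null. ImpE1 and the Lcp genes were also higher in the first library of each genotype, and the cause was not tested. The replicate block gave 961 higher and 1300 lower genes, with 2152 of 2446 calls shared. Genes near 3 counts per library cannot show a fall at this depth.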

Other observations

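The tests on chromosome arms, and the tests of explanations for the ecdysone and the fat body patterns, were chosen after the results were seen, and those on expression level and single libraries for chromosome 4 were set before their values were seen. Genes of chromosome 4, the small and largely heterochromatic chromosome, were lower in JIL-1 null more often than other genes. Of 64 tested, 23 fell (35.9%) and 4 rose, and 49 had a negative log2 fold change. The odds ratio of a fall against genes of the other arms was 2.74 (p = 0.000306, adjusted p = 0.000918, Fisher's exact test over 6 arms, across genes, which are not independent replicates). Camera with the preset correlation did not call the arm (adjusted p = 0.104, and adjusted p = 0.790 with an estimated correlation), although it did with limma-voom (0.00290) and without JIL-1 null library 1 (0.0378), over a range from 0.00290 to 0.790. Named here after their values were seen, CaMKI fell from 218 ± 14.96 to 101 ± 3.28 CPM (SD, n = 2), CG1732 from 31.5 ± 13.5 to 0.338 ± 0.478 CPM, MED26 from 115.3 ± 6.80 to 71.2 ± 1.34 CPM and zfh2 from 9.40 ± 0.672 to 3.78 ± 0.273 CPM, beside pho. The 4 genes that rose were CG11093, CR43957, CG31997 and ci.

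On the X chromosome, where JIL-1 is enriched in males, 11.7% of 1273 tested genes rose and 13.4% fell, and the median log2 fold change was 0.02. The sex of the larvae was not available, so neither these values nor those of the dosage compensation genes test the male X apart. Falls were less frequent than on the other arms (odds ratio 0.707, adjusted p = 0.000383, Fisher's exact test, again across genes that are not independent), and rises did not pass the threshold but also had an odds ratio below 1 (0.821, p = 0.0388, adjusted p = 0.233). Camera did not call the arm (adjusted p = 0.958). The larger autosome arms 2L, 2R, 3L and 3R had between 16.6% and 18.7% of genes lower. Near JIL-1 itself, 8 of the 20 tested genes nearest to it were called, against 31.8% of the other genes of the arm (p = 0.471, Fisher's exact test).

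In JIL-1 null 14 of 25 ecdysone early genes fell and 2 rose, while 9 of 10 late genes of the 71E puff rose and Eig71Eg fell, and the 4 ng genes rose. The camera calls of the early and late lists were lost with an estimated correlation (adjusted p = 0.798). That test rests on 2 residual degrees of freedom and called 0 lists, so it decides little here. If the null glands were only further along the glue-to-prepupa programme, the ng genes, expressed before the glue genes, would be lower, but their median log2 fold change was 1.84, with a largest standard error of 0.74. If the null glands were only less far along, the 71E late genes would not be higher, but their median was 4.20, with a largest standard error of 0.89. Both rises are part of the pattern to be explained, so these comparisons restate it and add no separate evidence. Pooled larvae of mixed ages could give both, and cannot be told apart from an effect of the mutation, because no value gives the ages within a library; the 2 null libraries differed from each other by a median log2 difference of 0.74 in the 71E late genes. The wild-type libraries differed by more, since library 1 was lower than library 2 by a median of 1.06 in these genes and higher by 1.07 in the ng genes, so a difference in stage between them stays possible. Without wild type libraries 1 and 2 in turn the median log2 fold change was 2.725 and 1.30 for the ng genes, and 3.60 and 4.115 for the 71E late genes. Loss of JIL-1 acting on these genes remains an open, untested hypothesis.

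The abundant fat body transcripts Fbp1 (29840 CPM in wild type), Lsp2 (15925 CPM) and Fbp2 fell while Lsp1gamma rose from a mean of 7.48 to 4335 CPM. Less fat body carried over with the null glands would lower all of its abundant transcripts alike, but over 6 of them the log2 fold changes spanned 1.57, from -1.65 for Fbp2 to -0.09 for Lsp1alpha, with a largest standard error of 0.16, so this alone does not explain the falls. The summed CPM of Lsp1alpha, Lsp1beta and Lsp1gamma went from 14726 to 16235 CPM. This difference of 1509 CPM, against a combined standard deviation of 1464 CPM, cannot decide whether reads were shared between the paralogs. The levels in each genotype argue against sharing at an equal rate in both as the source of the rise. Wild type held 14719 ± 1235 CPM (SD, n = 2) of Lsp1alpha and Lsp1beta beside 7.48 CPM of Lsp1gamma. JIL-1 null held less of these paralogs, 11901 ± 164 CPM, beside 4335 CPM of Lsp1gamma. A low Lsp1gamma allele in the wild-type strain cannot be told apart from an effect of the mutation, because strain and genotype are the same split and the highest wild-type level was 7.60 CPM. Which of these genes the gland itself expresses was not measured apart, and a change in fat body expression in the mutant may add to these and was not tested.

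The falls on chromosome 4 do not follow from expression level alone, since 0.14% of 10000 random lists of 64 genes with the same levels had a median as low as the observed -0.26. Such lists treat genes as independent, which those of a single chromosome may not be. A single library is not the cause either, since without each library in turn the median of the arm stayed at least 0.24 below that of all genes, with -0.245 as the highest value. A different chromosome 4 or strain background in the null stock cannot be told apart from an effect of the mutation, because both follow the genotype; the median lay at -0.29 relative to all genes. Loss of JIL-1 at this chromosome may contribute and was not tested further.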
